A study of Mus musculus with 6 samples.

How the data were processed

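Total RNA of J1 mouse embryonic stem cells treated for 6 h with 1 µM SC1 (3 samples) or DMSO (3 samples) was measured on 6 arrays, 1 per sample. Per the labels, the RNA was amplified and labelled with Cy3 for single-colour arrays. Per the submitters' processing notes, spots were quantified with Agilent Feature Extraction 10.7. The deposited files per array hold an intensity for each spot: a signal corrected for background and spatial trend, and the raw median intensity of the spot and of its local background. Per the file headers, other columns are 0 or 1 flags for spots well above background, outlying or saturated. The authors also deposited a matrix of log2 intensities; which method made it is not stated. Its values equalled quantile-normalized log2 signals to within a few hundredths, and each array had the same median, 5.18.

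Each array held 62976 spots, 59305 of them for 55681 distinct probes that are not controls. No spot was saturated, and 137 to 201 spots per array marked as outliers were left out. The 75th percentile of the processed signal was 532.2 to 539 on the DMSO arrays and 443.3 to 493.3 on the SC1 arrays. The log2 of the processed signal was averaged over spots of the same probe, and the array's 75th percentile was subtracted. Probes were kept when well above background on all 3 arrays of at least 1 group, which left 35321. A RefSeq gene table gave a symbol to 27235 probes by accession, and 16194 probes were named by 4610 genomic intervals (mm9) with a strand letter whose meaning the files do not give. Of these intervals 1067 were probed with both letters, and the letters were kept apart. One value per gene was used, the probe with the highest mean over the 6 arrays. Of 6343 genes with several probes 75 had probes called in opposite directions. Genes matched in the RefSeq table were called protein-coding or noncoding by its gene type, with pseudogenes left unclassified, and other genes by accession type. Intervals were counted as noncoding, and 5893 genes stayed unclassified (798 higher, 930 lower).

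SC1 was compared with DMSO with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). The samples, the tests, 24 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Each list was tested against the other genes with camera (preset correlation 0.01), adjusted over the 24 lists, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. Of the 10 calls of camera, 1 held with an estimated correlation. Members were also adjusted over the list alone. The share of changed RNAs in each class was compared with Fisher's exact test. Named genes were the 10 largest increases and decreases among genes with an official symbol that passed and did not overlap between groups, the 4 largest increases and decreases among noncoding RNAs, up to 4 members of each list with the smallest p among those that passed, and Mapk3 and Rasa1. The values of some genes that the rule names are not reported here.

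Alternatives were quantile normalization, the median of detected probes, normexp background correction (offset 50) with quantile or 75th percentile scaling, the deposited log2 matrix, no filter, a filter on all 6 arrays, the mean of a gene's probes, every probe tested, an intensity trend with a robust prior, array weights, the replicate number as a block, a plain linear model, stricter or unadjusted thresholds, signal matching and leaving out each array. Normexp used the median signal of each spot, because the files hold no mean signal. Scaling to 8 spike-in probe sequences and the slide column as a block were added after the data were seen. So were 9 further lists, used only among the other observations. The pipeline was tested on simulated data with 25416 genes and 200 changed ones: it recovered 8 of 50 changed 1.25-fold, 29 of 50 changed 1.5-fold, 38 of 50 changed 2-fold and 47 of 50 changed 4-fold. It called 5 unchanged genes and found the list that had been shifted, and 3 of 199 unchanged lists had an unadjusted camera p under 0.05. The simulated noise was independent between genes and the lists were random, so these list counts do not cover lists of correlated genes. With only 200 changed genes the adjusted threshold was also stricter than in the data, where 38.3% of genes were called. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.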

Results

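The comparison asked which messenger RNAs and long noncoding RNAs changed when mouse embryonic stem cells were exposed to SC1 for 6 h. SC1, also known as pluripotin, is a small molecule reported to inhibit both ERK1, a kinase of the FGF signalling pathway, and RasGAP, which switches RAS off. The cells were of the J1 line, derived from the inner cell mass of a 129S4/SvJae mouse and adapted to growth on gelatin-coated plates. The medium contained LIF (leukemia inhibitory factor), a cytokine that sustains self-renewal through STAT3. Samples received 1 µM SC1 or DMSO, the solvent used as control. Total RNA from 3 SC1 and 3 DMSO samples was labelled with Cy3 and hybridised to 6 single-colour arrays, each with 55681 distinct probes for genes and transcribed genomic intervals. Between 65.03% and 65.59% of these probes were well above background on the DMSO arrays, and between 63.2% and 65.1% on the SC1 arrays. The number of arrays limits the precision. Nothing in the labels says that the replicates were separate cultures, so each p measures the spread between these samples, which may be technical.

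After 6 h of SC1, Dusp6, Spry4, Egr1, Myc and Dusp4, all induced by ERK signalling, were among the most reduced messenger RNAs. Spic, a transcription factor gene of naive embryonic stem cells, and Cyp1a1, a cytochrome P450 gene induced by the aryl hydrocarbon receptor, were among the most increased. Of 24 gene lists fixed before the data were examined, 10 shifted relative to all other genes. ERK output, general pluripotency, formative and primed pluripotency, Wnt targets, ribosome biogenesis, cholesterol synthesis and glycolysis genes shifted down. Naive pluripotency, ATF4 and ER stress, and two-cell-like genes shifted up. With an estimated inter-gene correlation, the ERK output list alone kept its call. For the ribosome biogenesis, formative and primed, and two-cell-like lists the estimates were -0.0163, -0.00667 and 0.00128, below the preset 0.01. Stronger correlation among their members thus does not account for the calls these lists lost.

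Of 25439 genes and intervals tested with limma, 9751 (38.3%) changed at a Benjamini-Hochberg adjusted p under 0.05, of which 4612 rose and 5139 fell. A change of at least 2-fold was found for 1059 of them, 573 higher and 486 lower with SC1. The share that rose among the changed genes was 47.3%, against 52.1% with quantile normalization and 57.9% when the background was modelled with normexp before scaling to the 75th percentile, so which direction was more frequent depended on the scaling. With alternatives chosen after the data were seen, 5068 genes changed with spike-in scaling (2288 higher, 2780 lower) and 5543 with the slide column as a block. With normexp the count of genes changed at least 2-fold was 350 after quantile normalization (166 higher, 184 lower) and 351 after 75th percentile scaling (169 higher, 182 lower). With spike-in scaling 544 rose and 561 fell at least 2-fold, so the excess of increases turned under these 3 alternatives. The 3 SC1 arrays did not overlap the 3 DMSO arrays for 13254 genes (52.1%), against the 10% that random order gives. The first principal component held 73.1% of the variance and separated SC1 from DMSO. The SD of the log2 difference between 2 arrays was 0.22 to 0.26 within a group and 0.49 to 0.51 across groups.

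**Figure D1:**
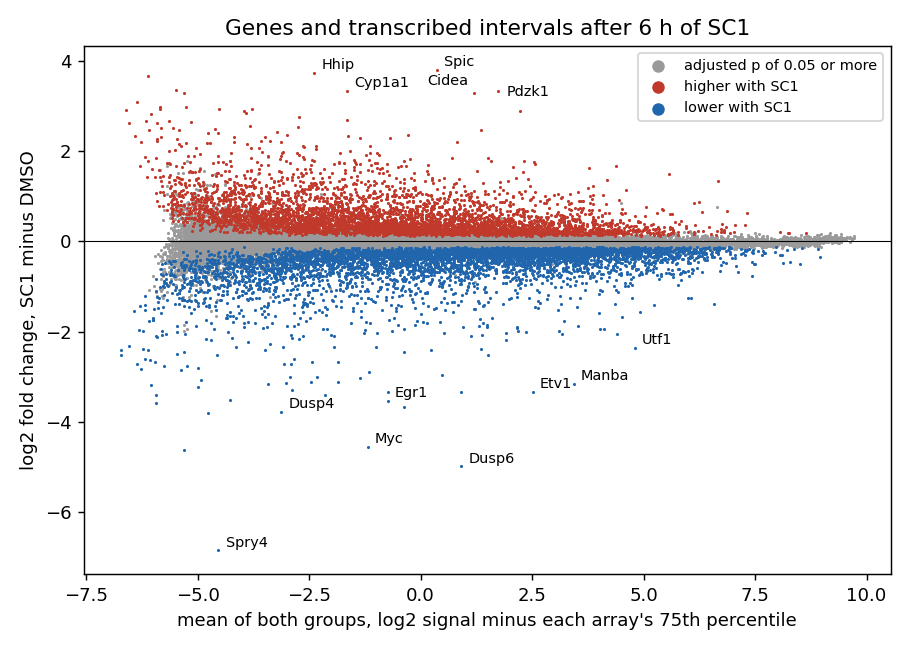
Log2 fold change (SC1 minus DMSO) of each of the 25439 genes and intervals tested against the mean log2 signal of both groups, relative to each array's 75th percentile. Red points are the 4612 that rose, blue points the 5139 that fell, and grey points those with an adjusted p of 0.05 or more; the fitted value of Spry4, which was not above background on any SC1 array, is not a measured fold.

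Spic rose most among named genes measured on all arrays, by a log2 fold change of 3.81 (SE 0.0532, n = 3 per group, adjusted p = 2.45e-06). Hhip, which encodes a decoy receptor for Hedgehog proteins, rose by 3.75 (SE 0.0975). Cyp1a1 rose by 3.35 (SE 0.0689), Pdzk1, a scaffold protein gene, by 3.34 (SE 0.0852) and Cidea, which encodes a lipid droplet protein, by 3.30 (SE 0.0603). These 4 genes had adjusted p values from 4.01e-06 to 1.05e-05. The other 5 of the 10 largest increases by fitted value were not above background on any DMSO array. For such genes a bound was made by setting the undetected arrays at the higher of the measured signal and the lowest signal called well above background on that array. Here and below, an adjusted p beside a bound belongs to the fitted log2 fold change, and the bound itself was not tested. Pirb rose at least 4.75-fold (adjusted p = 0.00322), Vit at least 4.35-fold (adjusted p = 3.19e-05), Cnga4 at least 3.11-fold (adjusted p = 0.000117), Slc25a48 at least 2.92-fold (adjusted p = 0.0052) and Qrfpr at least 2.11-fold (adjusted p = 1.35e-05). The fitted log2 fold change of Slc25a48 was 2.98, and 0.43 with normexp and quantile normalization. With the column of the slide as a block, the adjusted p of Slc25a48 was 0.0586.

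Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, fell at least 25.0-fold (adjusted p = 6.93e-07) and was not above background on any SC1 array. Dusp6, which encodes a phosphatase that inactivates ERK, had a log2 fold change of -4.99 (SE 0.0704), a 31.7-fold decrease. Myc, a growth-promoting transcription factor gene, fell 23.4-fold with a log2 fold change of -4.55 (SE 0.0601). Dusp4 had a log2 fold change of -3.78 (SE 0.0909), Robo4, a guidance receptor gene, -3.67 (SE 0.0702), and Egr1, an immediate early gene, -3.53 (SE 0.0455). Tnfsf11, the gene of the cytokine RANKL, fell at least 7.39-fold (adjusted p = 5.75e-05), the noncoding RNA Platr8 at least 6.82-fold (adjusted p = 2.65e-06) and Pirt at least 2.90-fold (adjusted p = 6.6e-05). Clnk fell (adjusted p = 0.000307) but was above background on only 1 of the 3 SC1 arrays, so no fold is given.

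Genes induced by ERK signalling fell together. Of 23 tested members of the ERK output list, 20 fell, 1 rose and 2 did not pass, and the counts were the same adjusted over the list alone (20 lower, 1 higher). Besides the genes above, Etv1, an ETS transcription factor gene, fell 10.1-fold (SE of log2 0.0415). Epha4 was the 1 gene that rose, by 0.61 on the log2 scale; it was named after its value was seen. The median log2 fold change was -1.09, also with Spry4 at its bound, and the list shifted down against other genes (camera adjusted p = 6.72e-12; adjusted p = 0.0497 with an estimated correlation).

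Messenger RNAs of the pathway itself moved less. Mapk3, which encodes ERK1, had a log2 fold change of -0.14 on its brightest probe (SE 0.0413, adjusted p = 0.0388) and -0.26 on another. Its adjusted p was 0.0556 to 0.106 when any 1 of the 6 arrays was left out and 0.0837 with the replicate number as a block. Over all alternatives it ran from 0.00994 with an intensity trend to 0.503 with spike-in scaling. Rasa1, which encodes the RasGAP p120, had a log2 fold change of -0.11 (SE 0.045, adjusted p = 0.107) and did not pass. Of 22 RAS and ERK components, 5 rose, 6 fell and 11 did not pass, with 5 higher and 6 lower adjusted over the list alone. Fgfr2, an FGF receptor gene, rose by 0.80 on its brightest probe and by 2.01 on another, and Fgfr1 rose by 0.42, with probes from 0.0096 to 0.42. Rasa2 and Rasa3, further RasGAP genes, fell by 0.44 and 0.36 on the log2 scale. With spike-in scaling the adjusted p of Fgfr1 was 0.0715 and that of Rasa3 was 0.0559. The components did not shift as a list (camera adjusted p = 0.932); their median was -0.040 while their mean and the test pointed up, and the median was above 0 with quantile normalization.

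**Figure D2:**
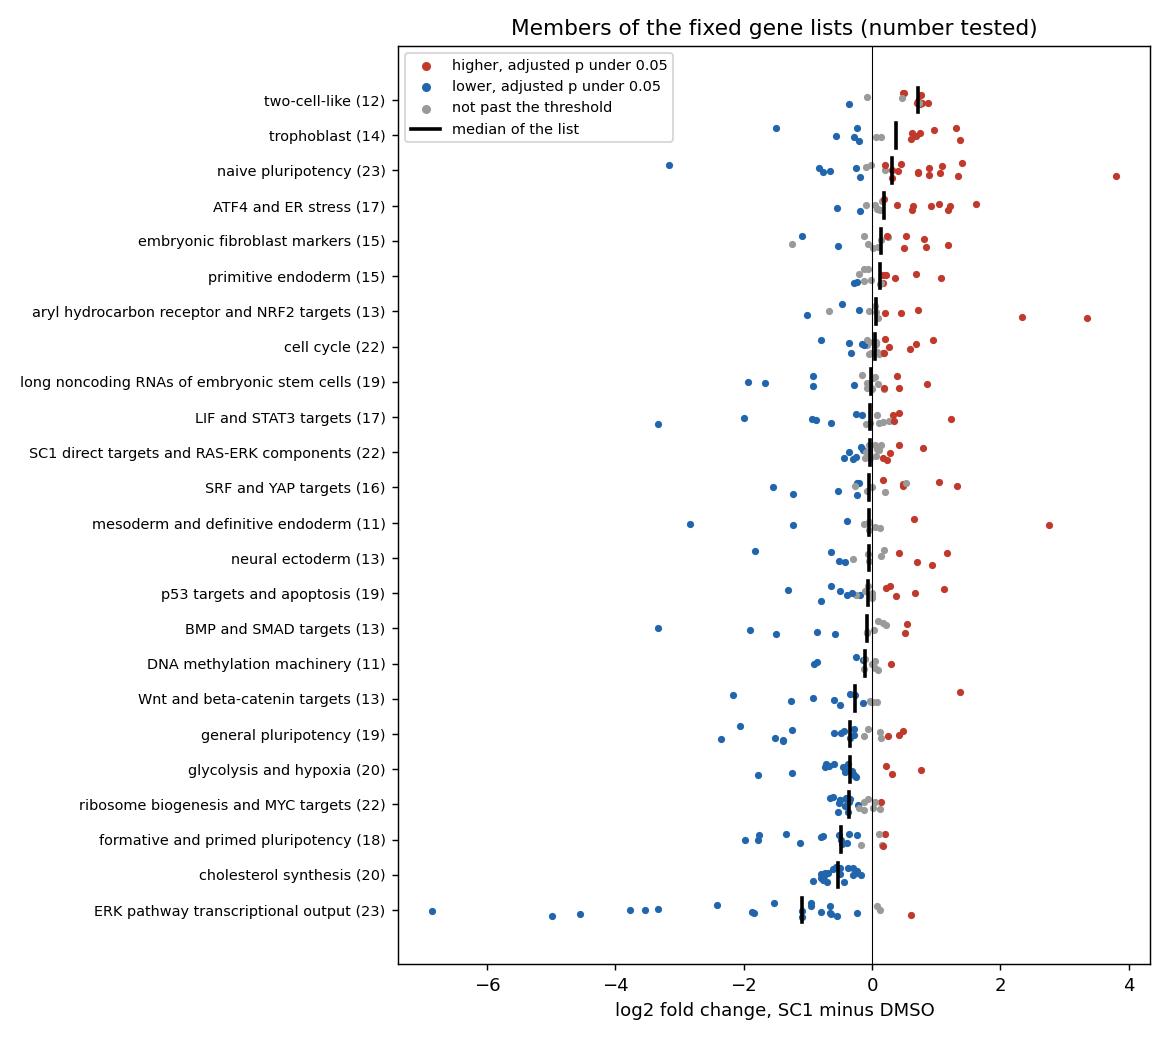
Log2 fold change (SC1 minus DMSO) of each tested member of the 24 fixed lists, with 1 point per gene and a black bar at the list's median. The ERK output list has the lowest median, -1.09, and the two-cell-like list the highest, 0.71; the medians of the mesoderm, neural, LIF, BMP, SRF and YAP, RAS-ERK component and long noncoding RNA lists lie just below 0 and were above 0 under at least 1 of the other scalings.

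Genes of naive pluripotency, the state of the preimplantation epiblast, rose more often than they fell. Of 23 members 14 rose, 6 fell and 3 did not pass, and 15 rose and 6 fell adjusted over the list alone. Spic rose 14-fold, Tfcp2l1, a transcription factor gene downstream of LIF and Wnt signalling, rose by 1.10 (SE 0.0416), and Crxos by 1.05, with probes from 0.18 to 1.06. Manba, which encodes a lysosomal mannosidase and is counted in this list, moved the other way and fell 8.93-fold. The list shifted up (median 0.31, camera adjusted p = 0.00582), a call lost with an adjusted p = 0.299 with an estimated correlation. Nanog and Esrrb, core regulators of this state chosen after their values were seen, had log2 fold changes of 0.21 and -0.018 and did not pass over all genes; Nanog passed adjusted over the list alone.

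General pluripotency genes fell. Of 19 members 12 fell, 3 rose and 4 did not pass, and 13 fell and 4 rose adjusted over the list alone. Utf1, a chromatin-bound factor of embryonic stem cells, fell 5.14-fold (SE of log2 0.053), Dppa2 4.16-fold (SE of log2 0.0481), Tdgf1, which encodes the Nodal co-receptor Cripto, 2.62-fold and L1td1, an RNA-binding protein gene, 2.61-fold. The median was -0.35 (camera adjusted p = 0.000689; adjusted p = 0.299 with an estimated correlation). Pou5f1, which encodes OCT4 and was chosen after its value was seen, had a log2 fold change of 0.12 and did not pass.

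Genes of formative and primed pluripotency, the states of the later epiblast, fell as well. Of 18 members 13 fell, 2 rose and 3 did not pass, and 14 fell and 4 rose adjusted over the list alone. Otx2, a transcription factor gene of the early postimplantation epiblast, fell 3.95-fold (SE of log2 0.063), Car14, a carbonic anhydrase gene, 3.44-fold, Foxd3 3.40-fold and Dnmt3b, a de novo DNA methyltransferase gene, 1.71-fold. The median was -0.48 (camera adjusted p = 0.00021; adjusted p = 0.069 with an estimated correlation).

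Markers of differentiated lineages moved in both directions. Among 11 mesoderm and definitive endoderm genes 2 rose, 3 fell and 6 did not pass, with the same counts adjusted over the list alone (2 higher, 3 lower; camera adjusted p = 0.59). Gsc, a homeobox gene of the organizer, rose by 2.76 (SE 0.218), Mesp1, a gene of early mesoderm, fell at least 1.87-fold (adjusted p = 0.000248), Mesp2 fell 2.35-fold and Eomes 1.31-fold. Among 15 primitive endoderm genes 6 rose, 2 fell and 7 did not pass, and 6 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.305). Pdgfra, a receptor gene of this lineage, rose by 1.07 (SE 0.059) and Lama1, a laminin gene, by 0.69. Sparc rose by 0.36 and Col4a1 fell by 0.28 on the log2 scale, but their adjusted p was 0.15 and 0.157 with spike-in scaling. Among 13 neural genes 4 rose, 4 fell and 5 did not pass, with the same counts adjusted over the list alone (4 higher, 4 lower; camera adjusted p = 0.932). Pax6, an eye and forebrain regulator, fell 3.55-fold, Zic1 fell 1.56-fold, and Dll1, a Notch ligand gene, and Tubb3, a neuronal tubulin gene, rose 2.24-fold and 1.92-fold. The neural median was -0.049 while the camera test pointed up, and the median was above 0 with normexp and 75th percentile scaling.

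Trophoblast genes, markers of the placental lineage, gave 7 higher, 5 lower and 2 not passing among 14, with 7 higher and 5 lower adjusted over the list alone. Tfap2c, a transcription factor gene of trophoblast and germ cells, rose by 1.37 (SE 0.0505), Tfap2a by 0.68, Ascl2 by 0.62 and Krt18, a keratin gene, by 0.61. As a list they did not pass (camera adjusted p = 0.0823), but they passed with spike-in scaling (adjusted p = 0.0271). They also passed on probes above background on all 6 arrays (adjusted p = 0.0355), a filter that removes Cdx2, which fell and was not above background on any SC1 array, so that pass is not independent of the change. Markers of embryonic fibroblasts, a cell type often used as feeder, gave 6 higher, 2 lower and 7 not passing among 15, with 6 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.279). Dcn, a matrix proteoglycan gene, rose by 1.18 (SE 0.0952), S100a6 by 0.83 and Col1a1, a collagen gene, by 0.81, while Thy1 fell 2.13-fold.

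Targets of other signalling pathways of embryonic stem cells were mixed. Among 17 LIF and STAT3 targets 4 rose, 7 fell and 6 did not pass, and 5 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.493). Gbx2, a homeobox gene that promotes self-renewal, fell 10.1-fold (SE of log2 0.0616), Noct, a gene of circadian metabolism, 3.98-fold and Socs2, a cytokine feedback gene, 1.92-fold. Among 13 BMP and SMAD targets 2 rose, 5 fell and 6 did not pass, with 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.32, and 0.0121 with spike-in scaling). Id3, which encodes an inhibitor of transcription factor binding, fell 10.2-fold (SE of log2 0.0603), Smad7, a feedback inhibitor, 3.73-fold and Bmp4, a ligand gene, 2.82-fold, while Id2 rose 1.45-fold.

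Wnt and beta-catenin targets fell. Of 13 members 8 fell, 1 rose and 4 did not pass, with 8 lower and 1 higher adjusted over the list alone. Wnt8a, a ligand gene, fell 4.47-fold (SE of log2 0.0931), Lef1, a transcription factor gene that binds beta-catenin, 2.40-fold, Ccnd2, a cyclin gene, 1.90-fold and Tcf7 1.51-fold. Dkk1, a secreted Wnt inhibitor gene named after its value was seen, rose (adjusted p = 0.0118) but was above background on only 1 of the 3 DMSO arrays, so no fold is given. The list's median was -0.26 (camera adjusted p = 0.0107; adjusted p = 0.357 with an estimated correlation). Among 16 SRF and YAP targets, genes of the cytoskeleton and of growth control, 5 rose, 6 fell and 5 did not pass, and 6 rose and 6 fell adjusted over the list alone. Myl9 and Tagln, contractile genes, rose 2.50-fold and 2.07-fold, while Lats2, a Hippo pathway kinase gene, fell 2.93-fold (log2 fold changes of its probes -1.55 and -0.72) and Ccn1, a secreted matrix protein gene, 2.34-fold. The SRF and YAP list did not shift (camera adjusted p = 0.932); its median was -0.045 while the test pointed up, and the median was above 0 with quantile normalization.

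Ribosome biogenesis, cholesterol synthesis and glycolysis lists each shifted down. Of 22 ribosome biogenesis and MYC target genes 14 fell, 1 rose and 7 did not pass, and 15 fell and 2 rose adjusted over the list alone. The nucleolar factors Wdr43, Nop2, Nolc1 and Ppan fell 1.57-fold, 1.52-fold, 1.42-fold and 1.34-fold, and the list's median was -0.35 (camera adjusted p = 0.000164; adjusted p = 0.069 with an estimated correlation). All 20 cholesterol synthesis genes fell, both over all genes and adjusted over the list alone (20 lower, 0 higher). Lss, the lanosterol synthase gene, fell 1.90-fold (SE of log2 0.0596), Sqle, the squalene epoxidase gene, 1.73-fold, Idi1 1.71-fold and Nsdhl 1.62-fold. The cholesterol list's median was -0.53 (camera adjusted p = 4.21e-09; adjusted p = 0.0628 with an estimated correlation). Of 20 glycolysis and hypoxia genes 17 fell and 3 rose, with the same counts adjusted over the list alone (17 lower, 3 higher). Pdk1, a kinase gene that restrains pyruvate oxidation, fell 3.41-fold (SE of log2 0.0581), the glucose transporter gene Slc2a1 2.39-fold and Ankrd37 1.64-fold, while Ndrg1, a hypoxia-induced gene, rose 1.70-fold. The glycolysis list's median was -0.35 (camera adjusted p = 0.000114; adjusted p = 0.364 with an estimated correlation).

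**Figure D3:**
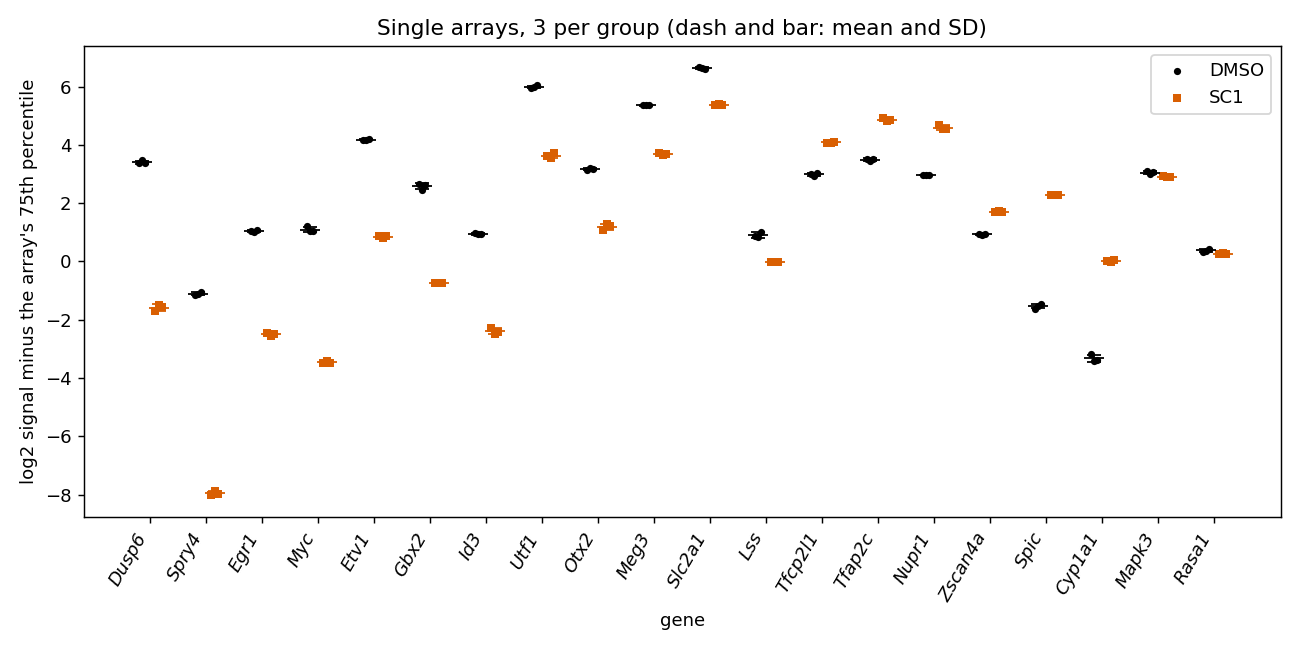
Log2 signal minus the array's 75th percentile on each of the 6 arrays for 20 of the genes named by the rule fixed before the data were examined; dashes and bars are the mean and SD of 3 arrays per group. SC1 and DMSO arrays do not overlap for Dusp6, Myc, Gbx2, Utf1 or Spic, nor for Mapk3 and Rasa1, whose log2 fold changes are -0.14 and -0.11; Spry4 on the SC1 arrays is at background.

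ATF4 and ER stress genes rose. Of 17 members 9 rose, 2 fell and 6 did not pass, and 10 rose and 2 fell adjusted over the list alone. Nupr1, a stress-induced chromatin protein gene, rose 3.08-fold (SE of log2 0.0568), Ddit3, which encodes CHOP, 2.32-fold, Atf5 2.26-fold and Atf3 2.06-fold. The median was 0.18 (camera adjusted p = 0.000777; adjusted p = 0.299 with an estimated correlation). The 2 members that fell, Xbp1 and Hspa5, had log2 fold changes of -0.55 and -0.19. They were named after their values were seen.

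Cell cycle and p53 genes moved both ways. Among 22 cell cycle genes 7 rose, 5 fell and 10 did not pass, with 7 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.445). The cyclin-dependent kinase inhibitor genes Cdkn2c, Cdkn1b and Cdkn1c rose 1.92-fold, 1.60-fold and 1.51-fold, and Ccne1, the cyclin E1 gene, fell 1.73-fold. Among 19 p53 targets and apoptosis genes 5 rose, 7 fell and 7 did not pass, with 5 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.445). Gdf15, a stress cytokine gene, rose 2.17-fold and Bmf 1.59-fold, while Pmaip1 and Bbc3, which encode the pro-apoptotic proteins NOXA and PUMA, fell 2.49-fold and 1.41-fold.

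Among 13 aryl hydrocarbon receptor and NRF2 targets 5 rose, 3 fell and 5 did not pass, with 5 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.279). Cyp1a1 rose 10.2-fold, Cyp1b1, another P450 gene, 5.03-fold and Nqo1, a quinone reductase gene, 1.65-fold, while Tiparp, also a receptor target, fell 2.01-fold. Of 12 two-cell-like genes, markers of rare cells that resemble the early cleavage embryo, 8 rose, 1 fell and 3 did not pass, and 9 rose and 1 fell adjusted over the list alone. Gm4340 rose 1.84-fold, Zscan4a 1.71-fold, Zscan4c 1.69-fold and Zscan4f 1.65-fold; probes of such closely related genes can share targets. The median was 0.71 (camera adjusted p = 0.000472; adjusted p = 0.0756 with an estimated correlation). Among 11 DNA methylation genes 1 rose, 4 fell and 6 did not pass, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.258, and 0.0357 with normexp and 75th percentile scaling). Tet1, a 5-methylcytosine oxidase gene, fell 1.88-fold, Dnmt3l, a methyltransferase cofactor gene, 1.82-fold and Uhrf1 1.20-fold. The adjusted p of Uhrf1 was 0.187 with spike-in scaling.

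Long noncoding RNAs known from embryonic stem cells moved in both directions. Of 19 tested 4 rose, 5 fell and 10 did not pass, with 4 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.49). Mirg and Meg3, maternally expressed RNAs of the imprinted Dlk1-Dio3 region, fell 3.80-fold (SE of log2 0.125) and 3.18-fold (SE of log2 0.0393). Malat1, a nuclear RNA, and Mir17hg, a microRNA host transcript, each fell 1.89-fold. Among noncoding RNAs above background on all arrays the largest increase was at an interval of chromosome 14 (mm9, 62280837 to 62283960, strand letter R), which rose by 2.57 (SE 0.0997; probes from 2.25 to 2.89). A neighbouring interval of chromosome 14 (mm9, 62294849 to 62301165, R) rose by 2.37 (SE 0.0505; probes from 2.37 to 2.94). The RNAs E030044B06Rik and 9530059O14Rik rose at least 4.68-fold (adjusted p = 0.000375) and at least 2.53-fold (adjusted p = 0.00224). The 4 largest decreases by fitted value, which for undetected RNAs does not establish a rank, were Platr8, an RNA named only by its accession that fell at least 3.19-fold (adjusted p = 0.00376), an interval of chromosome 16 (mm9, 13752215 to 13764390, F; log2 fold change -2.41) and an interval of chromosome 6 (mm9, 143053023 to 143069198, F; log2 fold change -2.27).

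Noncoding RNAs changed less often than protein-coding genes. Of 4010 noncoding RNAs 544 rose and 515 fell (26.4% changed), against 3270 and 3694 of 15536 protein-coding genes (44.8%; 3681 and 3223 with quantile normalization); the odds ratio was 0.442 (95% interval 0.409 to 0.477, Fisher's exact test, two-sided, p = 3.62e-103). For changes of at least 2-fold it was 0.787 (95% interval 0.653 to 0.945, Fisher's exact p = 0.00874), with 65 noncoding RNAs higher and 83 lower. Against protein-coding genes matched on mean signal the odds ratio was 0.502 (95% interval 0.457 to 0.553, Fisher's exact p = 2.73e-47), and with spike-in scaling of all genes it was 0.821 (Fisher's exact p = 1.25e-05). Genes are not independent replicates, so these p values describe counts of genes. Noncoding RNAs named by accession changed in 37.1% of 572 and genomic intervals in 24.6% of 3438. Of the intervals 745 were tested with both strand letters, and each of these was counted as 2 noncoding RNAs. At least 2-fold, 5.94% of those named by accession changed, a higher share than the 4.64% of protein-coding genes. For intervals it was 3.32%, so the lower share of noncoding RNAs at 2-fold came from the intervals. With the slide column as a block 612 noncoding RNAs and 3937 protein-coding genes changed, and with spike-in scaling 3283 protein-coding genes. Among changed noncoding RNAs 51.4% rose, against 74.9% with normexp and 75th percentile scaling (1170 higher, 393 lower) and 44% with spike-in scaling (318 higher, 405 lower), so the balance depended on the scaling.

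**Figure D4:**
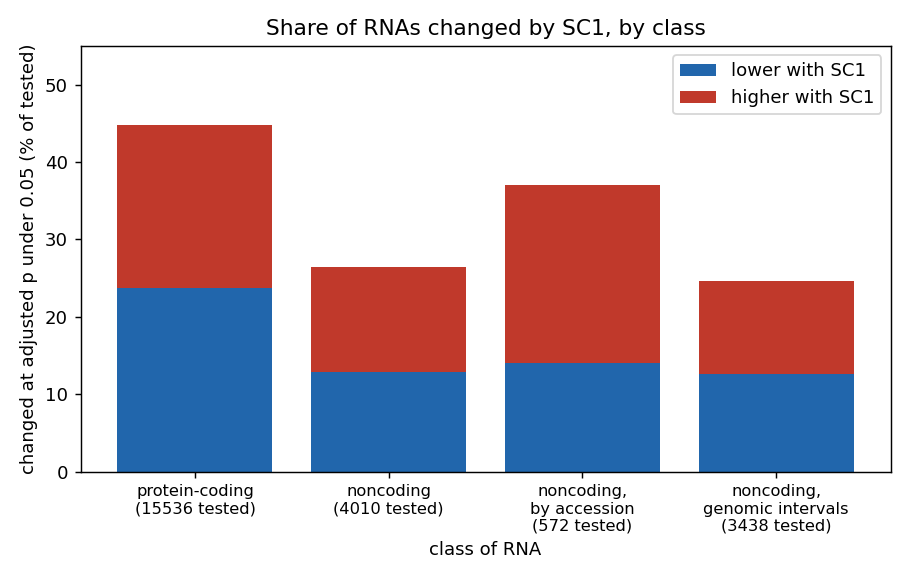
Percent of tested RNAs of each class that changed at an adjusted p under 0.05, with the part that fell in blue and the part that rose in red; the last 2 bars divide the noncoding class by how its probes are named. Protein-coding genes changed in 44.8%, noncoding RNAs in 26.4%.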

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

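The tests of the control probes were chosen only after the results were seen. The signal-matched comparison was planned, but its reading as a test of dimmer signals was set only after its value was seen.

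Control probes for ERCC RNAs, which the comparisons do not use, gave a signal on these arrays. Of 96 such probes, 12 were well above background on all 6 arrays, and 3 of these were higher on every SC1 array than on every DMSO array after scaling, while 0 were lower; without scaling 1 was higher and 4 were lower on every SC1 array. Such an order is expected by chance for 5% of probes in each direction. The log2 differences, SC1 minus DMSO, were 0.63, 0.21 and 0.17 (0.633, 0.21 and 0.169). Scaling to the 75th percentile, which was lower on the SC1 arrays, may account for the 2 smaller ones: without scaling they overlapped, with differences of 0.006 and -0.0343. It did not account for the largest, which was still higher on every SC1 array without scaling, by 0.43 (0.429). No biological explanation was tested; binding of a cellular RNA to this probe stays open.

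Fewer noncoding RNAs than protein-coding genes changed. Dimmer signals do not account for all of it, since the odds ratio against protein-coding genes matched on mean signal was 0.502 (95% interval 0.457 to 0.553). Neither does a larger spread between arrays, since after matching on signal and residual SD it was 0.514 (95% interval 0.467 to 0.566). Probes for genomic intervals, rather than annotated transcripts, may account for it: noncoding RNAs named by accession had an odds ratio of 0.815 (95% interval 0.638 to 1.04, Fisher's exact p = 0.102) against signal-matched protein-coding genes, 37.1% against 42%. With 572 such RNAs that interval also leaves room for a lower share of noncoding RNAs, and a biological difference between the classes stays open. The noncoding class counts 745 genomic intervals under both strand letters, and what this adds to its lower share was not tested.

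All 3 DMSO arrays and SC1 replicate 1 lay in 1 column of the slide and SC1 replicates 2 and 3 in the other, so position on the slide could have made the difference between groups. The column did not make all of the larger changes. Of 1004 genes that changed at least 2-fold between the replicates 2 and 3 of the groups, 99.2% (95% interval 98.44 to 99.66) moved the same way between SC1 replicate 1 and DMSO replicate 1, within 1 column. The interval treats genes as independent, which they are not, and rests on 1 pair of arrays. That pair lay in rows 4 and 1 of the column. Effects of the row, and smaller changes, were not tested. The median ratio of the log2 fold changes was 0.977. The SC1 treatment is the difference the design names. Of the 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05, 1 split, the real one, gave the largest result each time. It gave 9751 changed genes, 1059 changed at least 2-fold, 6964 protein-coding genes and 1059 noncoding RNAs, and the highest of the other splits gave 0 each. For gene lists the values were 10 and 6. Every other split puts SC1 and DMSO arrays on both sides, so the SC1 difference widens the spread within a side. Counts of 0 genes were thus close to set in advance, and no conclusion is drawn from the splits.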

How the results depend on the processing

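Spike-in scaling and the slide column as a block were chosen only after the results were seen. The count of genes changed at least 2-fold was 350 with normexp and quantile normalization and 351 with normexp and 75th percentile scaling, against 1059. These also start from the raw median signal and add an offset of 50. That offset exceeds the median processed signal of every array (31.91 to 38.73), so it shrinks the folds of dim genes by construction. How much of the drop it makes was not tested. With spike-in scaling 5068 genes changed (4562 of them also in the main count), 3283 of them protein-coding. The mean log2 spike-in signal of SC1 replicates 1, 2 and 3 was 13, 13.23 and 12.91. Their log2 75th percentiles relative to the DMSO mean were -0.117, -0.2227 and -0.2714. Spike-in scaling thus moved whole SC1 arrays apart, which widens the spread within the group. How much of the drop that makes was not tested. With the slide column as a block, which spends a degree of freedom and leaves the contrast to SC1 replicate 1 and the DMSO arrays, the counts were 5543 for all genes, 3937 for protein-coding genes and 612 for noncoding RNAs. A threshold of 0.01 gave 5792, 4243 and 584 by construction. All 10 shifted lists kept their call under the other alternatives run on lists, but an estimated correlation left 1, and fry, which does not compare with other genes, gave 20. Without 1 array at a time 7783 to 8446 genes changed, 7516 to 7931 of them also in the main count; 1036 to 1083 changed at least 2-fold, 5522 to 5969 protein-coding and 862 to 931 noncoding, the odds ratio was 0.48 to 0.501, and 10 lists shifted each time. The replicate numbers did not pair the arrays (correlations of deviations -0.0133, -0.0365 and -0.0154), and the replicate block gave 7910 genes. The odds ratio stayed between 0.373 and 0.821. Of 120 named genes 112 kept call and direction under every alternative that tested them; Mapk3, Sparc, Col4a1, Uhrf1, Fgfr1, Rasa3 and Slc25a48 were among those that lost their call under at least 1. Over all alternatives 2364 values of named genes kept their side of the threshold and 22 lost it; of list values 483 kept it, 9 lost it, 14 gained it and 22 changed sign without a call. The median of all genes lay between -0.045 and 0.042 under every scaling. A block for the slide or the scan was not run, since there was 1 of each. Signal over background limits folds of dim genes; named genes undetected on all arrays of a group are given as bounds.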

Other observations

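The further lists in this part, and hence all tests on them, and the test of neighbouring intervals were chosen only after the main results were seen, though before their own values were, except those of Meg3 and Mirg, which had been seen in a fixed list. The members named here from the further lists were chosen after their values were seen.

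Genes of lysosomes and TFEB targets, which serve degradation and recycling, shifted up as a list, though 12 of 23 did not pass singly. Of 23 tested 10 rose, 1 fell and 12 did not pass, with 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0376 over the 9 further lists; adjusted p = 0.306 with an estimated correlation). Lamp2, a lysosomal membrane protein gene, rose by 0.59 on the log2 scale, Npc1, a cholesterol transporter gene, by 0.47 and Hexa, a hexosaminidase gene, by 0.43. Of 14 fatty acid synthesis genes 9 fell, 2 rose and 3 did not pass, with 9 lower and 2 higher adjusted over the list alone; the list did not pass (camera adjusted p = 0.0557). Scd1, a stearoyl-CoA desaturase gene, fell 2.95-fold and Fads2, a fatty acid desaturase gene, 1.71-fold, while Thrsp rose 1.56-fold.

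In the imprinted Dlk1-Dio3 region, Meg3 and Mirg fell, while Dio3, a deiodinase gene, rose 2.75-fold and Dlk1 rose 1.11-fold, with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.619). Among 14 interferon response genes 5 rose, 4 fell and 5 did not pass, and 7 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.619); Rtp4 fell 3.25-fold and Ifitm1 rose 1.62-fold. Among 15 germline genes 3 rose, 4 fell and 8 did not pass, with 3 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.957). Of 18 oxidative phosphorylation genes 1 passed, Cycs, which fell 1.11-fold, and 0 passed adjusted over the list alone (camera adjusted p = 0.619). Of 20 ribosomal protein genes 0 passed with limma, over all genes or adjusted over the list alone (camera adjusted p = 0.957).

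Myc messenger RNA fell, and lower MYC activity is a candidate explanation for the fall of ribosome biogenesis genes. It predicts that nucleotide and one-carbon synthesis genes, a further group of MYC targets, shift down, and they did. Of 17 genes 9 fell, 1 rose and 7 did not pass, with 9 lower and 1 higher adjusted over the list alone. Their median log2 fold change was -0.14 (-0.1395; camera p = 0.00922, adjusted p = 0.0415; adjusted p = 0.506 with an estimated correlation). Ribosomal protein genes, which the prediction did not name, did not shift (median -0.011, camera adjusted p = 0.957). The test does not tell MYC from other regulators of the same genes.

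Activation of the aryl hydrocarbon receptor may explain why Cyp1a1 and Cyp1b1 were higher. It predicts that further receptor targets shift up. Of 10 genes on the further list 3 rose, 1 fell and 6 did not pass, with 4 higher and 1 lower adjusted over the list alone. The median was 0.17 (0.1725). The 3 that rose were Ahr, Scin and Slc7a5, and the 1 that fell was Il33. Ahr encodes the receptor itself, so the list does not hold receptor targets only. The camera p of 0.0317 met the threshold set in advance, but the adjusted p of 0.0713 did not pass (0.397 with an estimated correlation), and the stricter reading was taken after it was seen. Tiparp, a target of the receptor, fell, so the question stays open.

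Neighbouring genomic intervals may belong to 1 transcript or locus. Across 316 pairs of intervals with the same strand letter within 20000 bases, the log2 fold changes of neighbours had a Spearman rho of 0.218 (one-sided permutation p = 1e-04, the smallest that 10000 permutations give). Of 26 pairs with both called, 23 moved the same way. Some tested intervals lie inside others with the same letter, such as 13754656 to 13756647 inside 13752215 to 13764390 on chromosome 16 (F). For any such pairs among the 316, agreement can follow from probing the same stretch and does not test separate neighbours. The pair on chromosome 14 that prompted the question was left out. Strand letters of 1 interval correlated as well (rho 0.23 across 745 intervals), so a shared locus and a shared strand were not told apart. Where both letters were called, 30 intervals moved the same way and 11 moved in opposite ways. Intervals and genes are not independent replicates.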
